A study of Mus musculus with 6 samples.

How the data were processed

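RNA was sequenced from sorted cDC1s of HDM-exposed WT and Vps33b KO mice, in 3 libraries per group. Per the labels' protocols, RNA was taken with Trizol and read in pairs of 150 bases on an Illumina NovaSeq instrument. The deposited table holds raw counts per Ensembl gene, not normalized, for 32285 features and 6 libraries. HISAT2 2.0.5, HTSeq and the mm10 build are named in the submitters' processing notes. The HTSeq version, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of paralogs and of overlapping genes are uncertain. Columns were matched to samples through the library label in each sample's description. Gene names and positions came from the GENCODE M21 annotation of mm10, which named 32235 of the features (99.8%). Of the features, 13875 were at 0 in all 6 libraries.

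Genes were kept by edgeR's filterByExpr, which left 12568. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, KO against WT with no further term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 30.1%. CPM values are TMM-normalized. Vps33b was also tested by an exact permutation of log2 CPM.

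Of the processing choices, the samples, the tests, the 36 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 889 distinct genes in 933 memberships. Lists with at least 5 tested members, 34 in all, were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Where a symbol belonged to several features, the one with the highest total count was used, a choice made after the data were examined, when a member of 2 lists was found to match a duplicate. The genes named were 13 fixed genes, the 10 genes with the smallest p among named protein-coding genes with a mean of 5 CPM or more and no overlap of the groups, since none passed the threshold, and the 2 members of each list with the smallest p, of which 1 gene is not reported here. Other genes in the text are said to have been chosen after their values were seen.

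Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, removal of immunoglobulin, T-cell receptor and haemoglobin genes, the replicate number as a block, and each library left out in turn. Offsets for GC content and transcript length and limma-voom with library quality weights were added after the data were examined. No library was left out of the main comparison. Log2 CPM correlated between 0.965 and 0.98 within groups and between 0.964 and 0.98 across them, over genes, and no pair of libraries agreed within sampling noise.

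The test was checked on simulated counts for 12568 genes with 200 changed, and with a list of 40 more shifted, all at a mean of 5 CPM or more. It recovered 12%, 62%, 86% and 90% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, with 50 genes at each size. Of 143 calls 17 were false, or 11.9%, above the nominal 5%, and 4 genes were called when nothing was changed. A list shifted by 0.4 on the log2 scale was called with a preset correlation and had an adjusted p of 0.0518 with an estimated one. A list that fails with an estimated correlation is therefore not shown to be unchanged. With a preset correlation 0 of 20 random lists were called. The genes were simulated independently of each other, whereas members of real lists varied together (estimated correlation 0.49 for nuclear oxidative phosphorylation). The random lists therefore do not show how often the preset correlation gives false calls in the real data.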

Results

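Type 1 conventional dendritic cells (cDC1s), the dendritic cells specialised in presenting captured antigen to CD8 T cells, were sorted by flow cytometry from the mLN of C57BL/6 mice. All mice had received 50 µg of house dust mite extract (HDM) into the nose 24 h earlier. Read counts per gene were available for 3 wild-type (WT) libraries and 3 libraries from mice with a conditional deletion of Vps33b (KO). VPS33B is a Sec1/Munc18-family protein that acts with VIPAS39 in endosomal and lysosomal membrane trafficking. The series is described as a test of the effect of its loss on cDC1s. The WT libraries held 17826793, 14949229 and 18450678 counts and the KO libraries 13603695, 17434247 and 11755944, in replicate order. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

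Vps33b transcript was lower in every KO library than in every WT library. The gene (ENSMUSG00000030534) lies on the plus strand of chromosome 7 from 80269649 to 80291754 in mm10. The deposited table gives a total per gene, so reads from single exons could not be told apart. Its level was 16.2, 19.1 and 13.8 CPM (counts scaled to the library total) in the WT libraries and 5.0, 7.01 and 8.29 CPM in the KO libraries. The group means were 16.4 ± 2.69 CPM in WT and 6.77 ± 1.66 CPM in KO (SD, n = 3 each), so that 41.3% of the WT level was counted in KO. The log2 fold change was -1.28 ± 0.27 (SE), with an edgeR quasi-likelihood adjusted p of 0.834 over all genes tested. An exact two-sided permutation test of the 6 libraries gave p = 0.1, the smallest value that 3 against 3 can give. The labels do not state which exons were deleted, and reads from exons that remain would still be counted. Vipas39, which encodes the binding partner, was at 55.4 ± 6.83 CPM in WT and 56.5 ± 1.01 CPM in KO, a log2 difference of 0.03 ± 0.15.

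**Figure D1:**
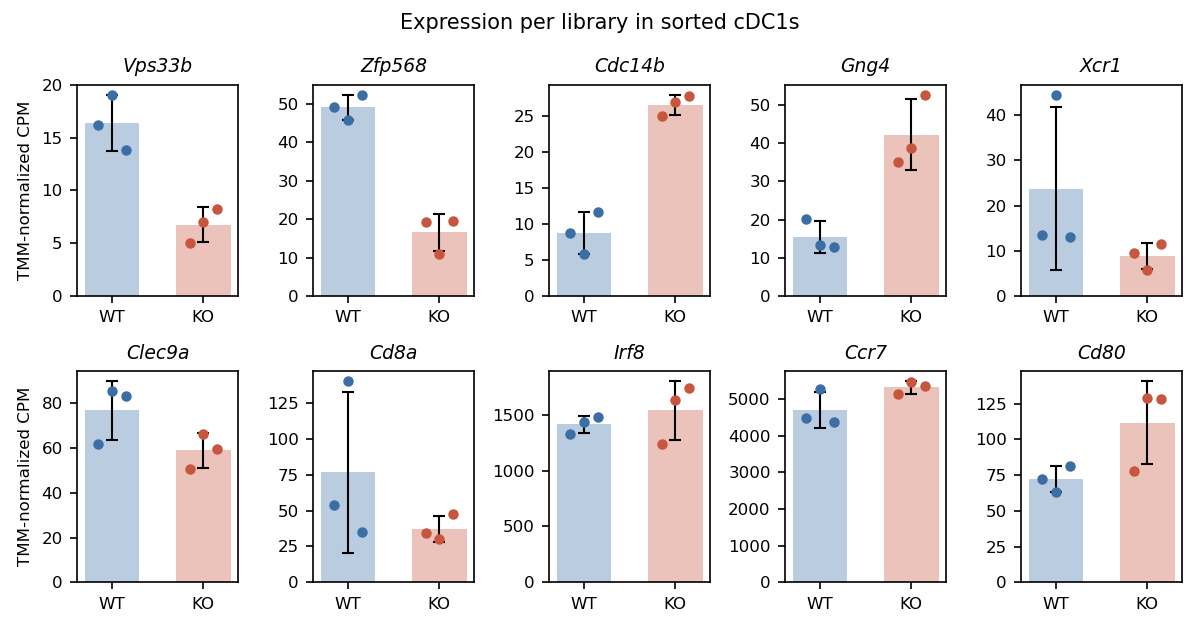
TMM-normalized CPM of 10 genes in the 3 WT (blue) and 3 KO (red) libraries. Bars are group means, error bars are SDs and points are single libraries; Vps33b, Zfp568, Cdc14b, Gng4 and Xcr1 do not overlap between the groups, and Xcr1 and Cd8a are highest in WT replicate 2, at 44.6 and 140.0 CPM.

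The comparison of KO with WT asks which transcripts of HDM-exposed cDC1s differ when Vps33b is deleted, and no single gene passed the test. Of 12568 genes tested by the edgeR quasi-likelihood test, 0 had an adjusted p under 0.05. At an unadjusted p under 0.05 there were 725 genes, 341 higher and 384 lower in KO, where 628 would be expected with no change at all. DESeq2 called 10 genes, limma-voom 0, and edgeR without an expression filter 3. The count at unadjusted p under 0.05 was 1621 without KO replicate 1, 376 without KO replicate 2 and 444 without KO replicate 3. In simulated data of the same size the test recovered 62% of genes changed 2-fold and 12% of genes changed 1.5-fold. Those data held 200 changed genes at a mean of 5 CPM or more. The adjusted threshold is easier to pass when many genes change, so these shares overstate the recovery where few do. The values of the groups did not overlap for 1338 genes, or 10.6%, where chance gives 10%.

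The genes with the smallest p-values had a difference of about 2-fold to 3-fold, and none of them passed. Zfp568 (ENSMUSG00000074221, chromosome 7, 29983955 to 30028282), which encodes a KRAB zinc-finger protein, was at 49.1 ± 3.25 CPM in WT and 16.6 ± 4.82 CPM in KO, a log2 fold change of -1.59 ± 0.22 with an adjusted p of 0.155. Cdc14b (ENSMUSG00000033102, chromosome 13, 64189268 to 64275290), a dual-specificity phosphatase, was at 8.77 ± 2.94 CPM in WT and 26.6 ± 1.40 CPM in KO, a log2 fold change of 1.57 ± 0.25. Gng4 (ENSMUSG00000021303, chromosome 13, 13784059 to 13827896), a G-protein gamma subunit, was at 15.4 ± 4.04 CPM in WT and 42.1 ± 9.30 CPM in KO, a log2 fold change of 1.44 ± 0.23. The adjusted p of both was 0.251. DESeq2 and edgeR without a filter called all 3 of these genes, with adjusted p-values of 2.86e-06 and 0.00576 for Zfp568, 0.000175 and 0.0217 for Cdc14b, and 0.00015 and 0.0217 for Gng4. Values lower in KO were also measured for Tk1, the cytosolic thymidine kinase (-1.37 ± 0.26), Pot1a, a telomere-end binding protein (-1.26 ± 0.25), and Lamb3, a laminin chain (-1.68 ± 0.35), all called by DESeq2. Vps13c, a lipid-transfer protein (-1.57 ± 0.36), and Cyth4, a cytohesin that activates Arf GTPases (-0.96 ± 0.23), were lower and Gramd2 (1.31 ± 0.31) was higher, each on the log2 scale, and neither DESeq2 nor edgeR called them. Exons of Tk1 share 1.6% of their bases with the opposite-strand gene Afmid, and those of Cdc14b 0.1% with Aaed1. Larger overlaps with opposite-strand genes were found for Ifi35 (16.8%), Psmb8 (14.7%), Xist (11.0%), March1 (7.6%), Hspe1 (7.6%) and Stx4a (5.2%), and Iglc2 shares 6.2% with the same-strand gene Iglj2 and Clec9a 5.6% with the same-strand gene Clec1b, so the counts of these genes are uncertain. Whether the counting used strand is not given in the sources used here.

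Both groups carried the transcripts of mature, migratory dendritic cells at high levels. Ccr7, the chemokine receptor that guides dendritic cells into lymph nodes, was at 4710 ± 492 CPM in WT and 5320 ± 172 CPM in KO, a log2 fold change of 0.18 ± 0.12. The list of the mature CCR7 programme rose in KO by camera, with 31 of 38 tested members above 0 and a median log2 fold change of 0.17 (adjusted p = 0.00107 with a preset correlation). With an estimated correlation its adjusted p was 0.661, and without KO replicate 2 its median was 0.11. The mean score of its members, on the centred log2 scale, was -0.08, -0.12 and -0.09 in the WT libraries and -0.05, 0.15 and 0.19 in the KO libraries. No member passed over all genes or when adjusted over the list alone. At an unadjusted p under 0.05, 4 members were higher and 1 was lower. The smallest p-values were those of the co-stimulatory ligand gene Cd80 (0.63 ± 0.19) and of Tnfrsf4, which encodes OX40 (0.40 ± 0.13). Cd86 was at 301 ± 33.1 CPM in WT and 396 ± 134 CPM in KO, and Il12b, a subunit of interleukin-12, at 991 ± 191 and 1130 ± 144 CPM.

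Genes of cDC1 identity fell as a list with a preset correlation. Their summed level hardly differed, at 6480 ± 506 CPM in WT and 6390 ± 371 CPM in KO. Of 30 tested members, 22 lay below 0, 8 were lower and 0 higher at an unadjusted p under 0.05, and the median log2 fold change was -0.29 (camera adjusted p = 0.00107 with a preset correlation). With an estimated correlation the adjusted p was 0.661, and without KO replicate 1 the median was -0.22 with an adjusted p of 0.169. With the members that another list also holds left out the median was -0.14 (adjusted p = 0.0239 with a preset correlation). No member passed over all genes, and 4 were lower when adjusted over the list alone. These were Sept3 (-2.00 ± 0.44), Ppt1, a lysosomal thioesterase (-0.67 ± 0.16), Wdfy4, needed for cross-presentation by cDC1s (-0.89 ± 0.25), and Itgax, which encodes CD11c (-0.56 ± 0.16). Sept3 and Ppt1 come from the rule for named genes, whereas Wdfy4 and Itgax were chosen after their values were seen. Xcr1, the chemokine receptor typical of cDC1s, was at 23.7 ± 18.1 CPM in WT and 8.84 ± 2.87 CPM in KO, and WT replicate 2 alone had 44.6 CPM. Clec9a, a receptor for dead cells, was at 76.9 ± 13 and 59.0 ± 7.81 CPM. Cd8a was at 76.6 ± 56.1 CPM in WT, with 140.0 CPM in WT replicate 2, and at 37.2 ± 8.93 CPM in KO, and Itgae had a log2 fold change of -0.47 ± 0.26. The transcription factors Irf8 (0.12 ± 0.14) and Batf3 (0.09 ± 0.15) differed by less than the spread. The list held its direction without WT replicate 2, with a median of -0.20. The mean score of its members, on the centred log2 scale, was 0.07, 0.45 and 0.08 in the WT libraries. In the KO libraries it was -0.38, -0.17 and -0.06.

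The list of endocytic and pattern-recognition receptors fell too, with a preset correlation. Its median log2 fold change was -0.26 over 37 tested members, with 24 below 0, and 6 lower and 0 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00491 with a preset correlation). The adjusted p was 0.661 with an estimated correlation. Without KO replicate 1 the median was -0.15 with an adjusted p of 0.275, and with the members that another list also holds left out it was -0.17 with an adjusted p of 0.11. The median was also -0.17 without WT replicate 2 (adjusted p = 0.0217) and with GC and length offsets (adjusted p = 0.00163). Without KO replicate 3, the library with the most monocyte transcripts, it was -0.39 (adjusted p = 4.4e-07), and the monocyte and pDC lists passed downward there too. The members with the smallest p-values were Cd14, the lipopolysaccharide co-receptor (-1.75 ± 0.41), and Havcr2, which encodes TIM-3 (-0.66 ± 0.21). Neither passed over all genes, and 0 members passed when adjusted over the list alone. Cd14 is also a monocyte marker, and it did pass when adjusted over that list alone. Siglech (-2.32 ± 0.78) is also in the pDC list.

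Genes of MHC class I presentation rose as a list. Of 26 tested members, 22 lay above 0, with a median log2 fold change of 0.15 (camera adjusted p = 0.00834 with a preset correlation, adjusted p = 0.661 with an estimated correlation). No member passed over all genes or when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. These were Stx4a, a SNARE protein (0.33 ± 0.12), and Psmb8, an immunoproteasome subunit (0.36 ± 0.15). H2-K1 was at 5370 ± 511 CPM in WT and 5900 ± 234 CPM in KO, and its reads may be shared with near-identical class I genes. Without WT replicate 3 the median was 0.10 with an adjusted p of 0.123, and without KO replicate 3 it was 0.12 with an adjusted p of 0.0916. The MHC class II list did not pass (17 tested, median -0.15, adjusted p = 0.785). Its members with the smallest p-values were March1, a ubiquitin ligase for class II (-1.76 ± 0.60), and H2-Ob (-0.87 ± 0.35). H2-Ab1 was at 674 ± 306 CPM in WT and 544 ± 39.2 CPM in KO. Without WT replicate 2 the class II median was 0.16.

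The lysosome list rose by a small amount with a preset correlation, with no member passing, and the list of endosomal fusion did not pass. The lysosome list had 34 of 48 tested members above 0 and a median log2 fold change of 0.12 (camera adjusted p = 0.0436 with a preset correlation, adjusted p = 0.661 with an estimated correlation), and 0 members passed when adjusted over the list alone. Lamp2 (0.40 ± 0.14) was among its higher members, while Ppt1, which is also in the cDC1 list, was at -0.67 ± 0.16. The list summed to 13000, 14200 and 12500 CPM in the WT libraries and to 13300, 14200 and 15400 CPM in the KO libraries. The highest sum was in KO replicate 3, the library with the most monocyte transcripts, and a part of these in the rise was not tested. The lysosome call was lost without a filter (adjusted p = 0.0577), and without WT replicate 1 (0.10, adjusted p = 0.14), WT replicate 3 (0.12, adjusted p = 0.179), KO replicate 2 (0.12, adjusted p = 0.0881) or KO replicate 3 (0.06, adjusted p = 0.412), and the median was 0.19 without WT replicate 2. The list of VPS33B partners, HOPS, CORVET and endosomal fusion had a median of 0.09 over 47 tested members (adjusted p = 0.191), with Vps26a of the retromer (0.41 ± 0.13) and Rab11a of recycling endosomes (0.36 ± 0.15) at the smallest p-values. Its median was 0.04 without KO replicate 2 and 0.05 without WT replicate 2 or KO replicate 3. The autophagy list had a median of 0.01 over 29 members (adjusted p = 0.959), with Gabarap at 0.34 ± 0.14 and Atg5 at 0.37 ± 0.16.

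The list of nuclear genes of oxidative phosphorylation rose with a preset correlation, and no member passed on its own. It summed to 3490, 3820 and 3450 CPM in the WT libraries and to 3640, 4440 and 4240 CPM in the KO libraries. The highest sums were in WT replicate 2 and KO replicates 2 and 3. Mitochondrial genes also held the largest share of counts there (2.43, 2.52 and 2.34%, against 1.81 to 1.98% in the other libraries). Of 42 tested members, 40 lay above 0, with a median log2 fold change of 0.23 (camera adjusted p = 3.32e-06 with a preset correlation, adjusted p = 0.661 with an estimated correlation). The median was 0.13 without KO replicate 2 (adjusted p = 0.0164), 0.32 without KO replicate 1 and 0.15 with GC and length offsets (adjusted p = 0.00232). At an unadjusted p under 0.05, 4 were higher, and none passed over all genes or when adjusted over the list alone. Ndufv2 of complex I (0.32 ± 0.13) and Sdhc of complex II (0.52 ± 0.21) had the smallest p-values. Transcripts differed with length over all genes, with a median log2 fold change of 0.11 in the shortest and -0.08 in the longest of 4 equal groups of genes, and the members of this list are short. All 13 mitochondrially encoded genes lay above 0 (median 0.14, adjusted p = 0.0992), with mt-Cytb at 0.24 ± 0.13 and mt-Nd1 at 0.20 ± 0.14. The list summed to 17800, 24600 and 19400 CPM in the WT libraries and to 17800, 25700 and 24300 CPM in the KO libraries. WT replicate 2 thus lay with KO replicates 2 and 3, and KO replicate 1 with the other WT libraries. Without WT replicate 2 and without KO replicate 1 that list passed, with medians of 0.25 and 0.30 and adjusted p-values of 0.00813 and 0.000696, as it did with DESeq2 (0.016), limma-voom (0.0198) and quality weights (0.000101). Its median was 0.03 without KO replicate 2 (adjusted p = 0.752), 0.07 without WT replicate 1 (0.691), 0.09 without KO replicate 3 (0.406) and 0.06 with GC and length offsets (0.799). With those offsets the median of all genes was 0.047.

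**Figure D2:**
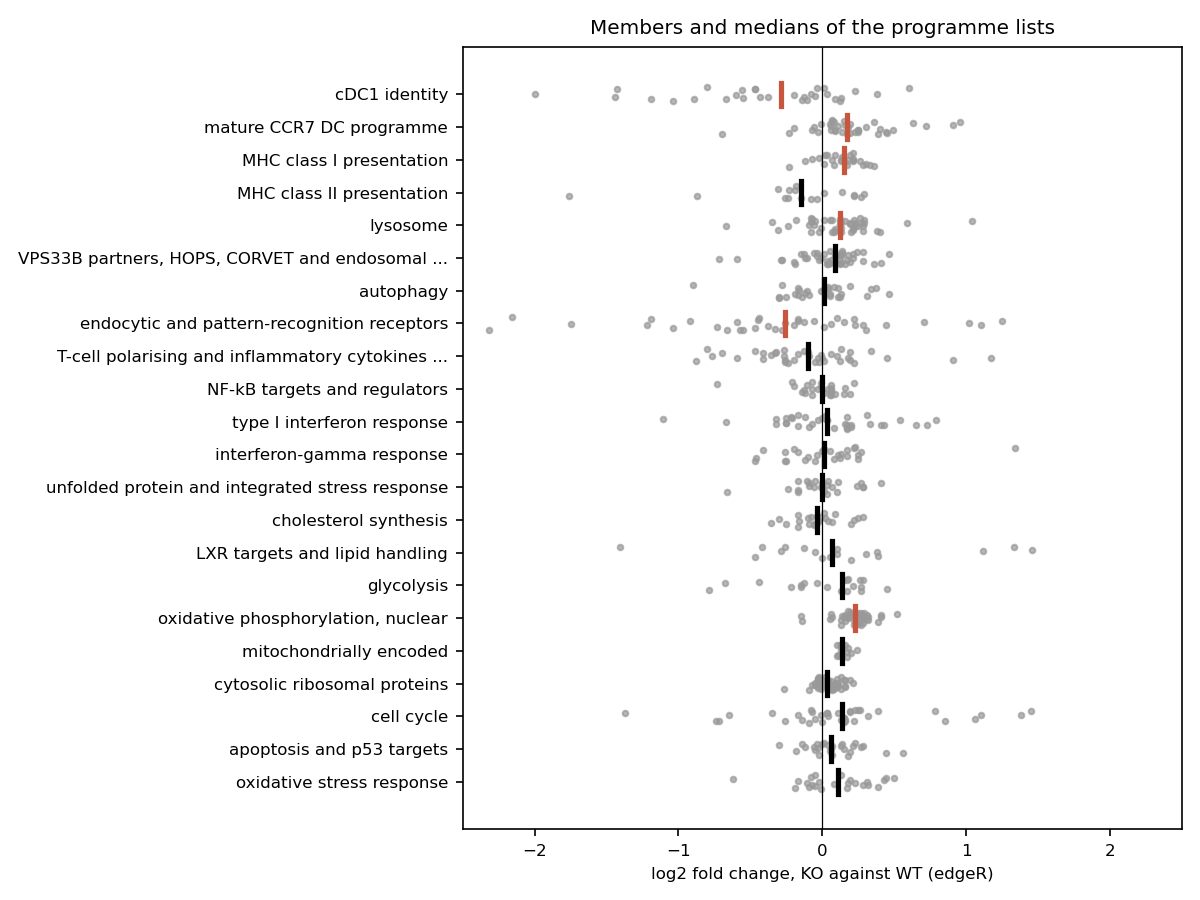
log2 fold change of KO against WT for each tested member (grey points) of the programme lists, with the list median as a bar, red for lists past an adjusted p of 0.05 by camera with a preset correlation. The median of the nuclear oxidative phosphorylation list lies at 0.23 and that of the cDC1 identity list at -0.29, and none of the lists passed with an estimated correlation.

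No other programme list passed. The cytokine and chemokine list had a median of -0.10 (39 tested, adjusted p = 0.202, and 0.0304 with GC and length offsets), with Itgb8, an integrin subunit that activates TGF-beta (-0.77 ± 0.24), and the neutrophil chemokine Cxcl2 (-0.80 ± 0.32) lowest in p. Its median was -0.04 without WT replicate 2 (adjusted p = 0.476) and with quality weights (0.195), and -0.06 with limma-voom (0.11). The list of NF-kB targets (26 tested, median 0.00, adjusted p = 0.908) held Ptgs2 (-0.73 ± 0.41) and Tnfaip3 (-0.21 ± 0.14). The type I interferon list had a median of 0.03 (35 tested, adjusted p = 0.785), with Ifi35 at 0.33 ± 0.14 and Cmpk2 at -1.11 ± 0.50, and passed without WT replicate 2 (0.33, adjusted p = 0.00498), without KO replicate 1 (0.26, adjusted p = 0.0309) and with quality weights (0.27, adjusted p = 0.015), while its median was -0.20 without WT replicate 3 (0.287) and -0.16 without KO replicate 3 (0.198). The interferon-gamma list had a median of 0.01 (27 tested, adjusted p = 0.849), with the guanylate-binding proteins Gbp9 at -0.41 ± 0.13 and Gbp4 at -0.25 ± 0.12. The unfolded protein list had a median of 0.00 (25 tested, adjusted p = 0.849), with Ppp1r15a at -0.24 ± 0.13 and Manf at 0.28 ± 0.17. Cholesterol synthesis had a median of -0.04 (24 tested, adjusted p = 0.849), with Insig1 at -0.36 ± 0.20, and passed without KO replicate 3 (-0.26, adjusted p = 0.0208), while its median was 0.11 without WT replicate 3 (0.204). LXR targets had a median of 0.07 (18 tested, adjusted p = 0.785), with Cd36 at -0.47 ± 0.19 and Fabp5 at 1.12 ± 0.48.

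Lists of metabolism, growth and stress did not pass either. Glycolysis had a median of 0.14 (20 tested, adjusted p = 0.785), with Pdk1 at -0.79 ± 0.27 and Slc16a3 at 0.45 ± 0.23, and its median was 0.03 without KO replicate 3, 0.04 without KO replicate 2, 0.06 without WT replicate 3, 0.08 without WT replicate 1 and 0.09 without WT replicate 2. Cytosolic ribosomal proteins had a median of 0.03 (59 tested, adjusted p = 0.202), with Rpl10 at 0.21 ± 0.14 and Rps2 at 0.19 ± 0.17, and passed without WT replicate 2 (0.25, adjusted p = 1.64e-13) and with quality weights (0.000101), while its median was -0.10 without WT replicate 3 (0.287). The cell cycle list had a median of 0.14 (38 tested, adjusted p = 0.785), with Mki67 at -0.72 ± 0.23 and with Tk1 lower when adjusted over the list alone. Apoptosis and p53 targets had a median of 0.06 (27 tested, adjusted p = 0.392), with Casp9 at 0.44 ± 0.21 and Bcl2l11 at -0.30 ± 0.18. That median was 0.02 without KO replicate 1 and 0.12 without KO replicate 3. The oxidative stress list had a median of 0.11 (24 tested, adjusted p = 0.117), with the glutathione peroxidases Gpx4 at 0.44 ± 0.18 and Gpx1 at 0.43 ± 0.18, and passed without WT replicate 2 (0.16, adjusted p = 0.028), with DESeq2 (0.0468) and with quality weights (0.015). The immediate-early and dissociation list, a sign of cell handling, had a median of -0.19 (31 tested, adjusted p = 0.0921), with Hspe1 at 0.49 ± 0.17 and Btg2 at -0.49 ± 0.20. It passed without WT replicate 3 (-0.31, adjusted p = 0.00666) and without KO replicate 1 (-0.35, adjusted p = 0.00781), and with DESeq2 (0.00976), limma-voom (0.0102), GC and length offsets (0.0468) and quality weights (0.0131). Its median was -0.07 without WT replicate 2 (adjusted p = 0.848), -0.14 without KO replicate 2 and -0.13 without KO replicate 3.

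Some lists of other cell types varied from library to library. The monocyte and macrophage list summed to 752 CPM in KO replicate 3 and to between 194 and 405 CPM in the other libraries, and Lyz2, chosen after its values were seen, was at 468 CPM in that library. Its median was -0.02 (16 tested, adjusted p = 0.37), with Cd14 at -1.75 ± 0.41 and Ccr2 at -1.09 ± 0.56, and without KO replicate 3 it was -1.17 with an adjusted p of 6.1e-05. The cDC2 list (16 tested, median -0.03, adjusted p = 0.785) held Cd300a at -1.86 ± 0.75 and Irf4 at 0.47 ± 0.22. The pDC list (12 tested, median -0.48, adjusted p = 0.117) held Siglech at -2.32 ± 0.78 and Ly6d at -1.61 ± 0.63, and passed without WT replicate 1 (-0.51, adjusted p = 0.0482) and without KO replicate 3 (-0.50, adjusted p = 0.0178), while its median was -0.13 without WT replicate 3 (0.497) and -0.27 without KO replicate 2 (0.518). The T cell list had a median of 0.23 (21 tested, adjusted p = 0.37), with Cd4 at -0.89 ± 0.30 and Cd5 at 0.76 ± 0.41, and passed without WT replicate 1 (0.31, adjusted p = 0.0376), while its median was 0.04 without WT replicate 3 (0.885) and 0.06 without KO replicate 1 (0.871). The NK and innate lymphoid list had a median of 0.15 (13 tested, adjusted p = 0.117), with Gzma at 0.09 CPM in WT and 1.26 ± 0.339 CPM in KO and Prf1 at 0.83 ± 0.70, and passed without WT replicate 1 (0.25, adjusted p = 0.0364), while its median was 0.04 without WT replicate 3 (0.322). The B cell list (18 tested, median 0.00, adjusted p = 0.849) held Iglc2 at 1.64 ± 0.74 and Cr2 at 0.85 ± 0.50, and its median was 0.51 without WT replicate 2, 0.44 without KO replicate 1, 0.36 with quality weights and -0.22 without KO replicate 3. Iglc2 was low, at 0.476 CPM in WT and 1.43 CPM in KO. The plasma cell list (8 tested, median -0.18, adjusted p = 0.959) held Ighg2c at -1.91 ± 0.85 and Prdm1 at -0.47 ± 0.26.

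Traces of tissue cells and blood were also present. The stromal and endothelial list had a median of -0.10 and an upward camera direction (11 tested, adjusted p = 0.402), with Dcn at 2.24 ± 0.77 and Col3a1 at 3.06 ± 1.19. Both were low and overlapped between the groups. Dcn was at 1.08 ± 0.357 CPM in WT and 5.69 ± 4.62 CPM in KO, and Col3a1 at 0.541 ± 0.937 and 4.36 ± 3.65 CPM. The epithelial list had a median of 0.06 and a downward camera direction (7 tested, adjusted p = 0.871), with Ager at -1.70 ± 0.79 and Sftpc at 1.83 ± 0.89. These 2 were also low, at 1.98 and 0.476 CPM in WT and 0.664 and 1.53 CPM in KO. Erythroid genes passed with a preset correlation (5 tested, median 1.24, adjusted p = 0.0477) and not with an estimated correlation (adjusted p = 0.661). Their sum was 113 CPM in WT replicate 3, 191 CPM in KO replicate 1 and 116 CPM in KO replicate 2, against 17, 11.8 and 19.6 CPM in the other libraries. Hba-a2 had a log2 fold change of 1.38 ± 1.43 and shares its sequence with Hba-a1, and Car2 was at 0.38 ± 0.24. The erythroid call was lost without WT replicate 1 (adjusted p = 0.11), WT replicate 2 (0.392), KO replicate 1 (0.275) or KO replicate 2 (0.187), without a filter (0.159), with DESeq2 (0.167), with offsets for GC content and length (0.156), with library quality weights (0.0698) and with members of several lists left out (0.0556), and its median was 4.17 without WT replicate 3 and 0.45 without KO replicate 1. Only 3 members each of the neutrophil list, with S100a8 at 1.49 ± 0.82 and Csf3r at 0.67 ± 1.01, and of the eosinophil, basophil and mast cell list, with Kit at -0.30 ± 0.17 and Prg2 at 0.54 ± 0.56, were measured, too few for the test. S100a8, Csf3r and Prg2 were at 0.605, 0.928 and 1.36 CPM in WT and at 1.9, 1.61 and 1.85 CPM in KO. The eosinophil, basophil and mast cell list summed to 53.7 ± 3.84 CPM in WT and 43.9 ± 7.69 CPM in KO, with no overlap. Most of this was Kit alone, at 51.7 ± 3.28 CPM in WT and 41.6 ± 8.3 CPM in KO. The sex-linked list (5 tested, median 0.01, adjusted p = 0.959) held Kdm5d at -0.36 ± 0.23 and Xist at 0.37 CPM in WT and 1.24 CPM in KO.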

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

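The offsets for GC content and length and the library quality weights were chosen after the data were examined. Vps33b was lower under all alternatives, from -1.42 to -1.11, and passed under none, with adjusted p-values from 0.0506 (DESeq2) to 1. No single gene passed with edgeR or limma-voom on the filtered table, whereas the count was 3 with no filter, 10 with DESeq2 and 0 to 7 with a library left out. DESeq2 called Zfp568, Gng4, Cdc14b, Rarres2, Fcna, Tk1, Pot1a, Lamb3, Slc27a3 and Gm31718; the last had 0 counts in each KO library, and Rarres2, Fcna, Slc27a3 and Gm31718 were named after their values were seen. The number of lists called was 7, against 0 with an estimated correlation, 0 with fry, 11 with quality weights and 5 to 10 with a library left out. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.005, 0.028 and -0.001; no KO library correlated best with its own number). With the replicate block 0 genes and 6 lists passed, with 942 genes at unadjusted p under 0.05, and the monocyte and macrophage median was 0.06; the lysosome and erythroid calls were lost (adjusted p = 0.062 and 0.136) and the mitochondrially encoded list passed (0.0383). Medians that turned sign, none of them a called list, follow; the cause was not tested. With no filter the plasma cell median was 0.11 and the stromal one 0.27. With limma-voom the stromal median was 0.62, the interferon-gamma one -0.02 and the epithelial one -0.44. With DESeq2 the monocyte median was 0.09, and with members of several lists left out 0.07. With the offsets the monocyte and cDC2 medians were 0.01 and the ribosomal one -0.02. With quality weights the interferon-gamma median was -0.03, the sex-linked one -0.05 and Vipas39 -0.01. With a library left out the ranges were -0.76 to 0.30 (plasma cell), -0.22 to 0.51 (B cell, at 0.00 with all libraries), -0.19 to 0.54 (stromal), -1.17 to 0.45 (monocyte), -0.08 to 0.09 (interferon-gamma), -0.19 to 0.89 (epithelial), -0.06 to 0.02 (autophagy), -0.20 to 0.33 (type I interferon), -0.10 to 0.25 (ribosomal), -0.20 to 0.05 (cDC2), -0.29 to 0.16 (MHC class II), -0.26 to 0.11 (cholesterol), -0.01 to 0.26 (cell cycle), -0.11 to 0.08 (sex-linked), -0.07 to 0.10 (LXR), -0.07 to 0.11 (Vipas39), -0.52 to 0.12 (H2-Ab1) and -0.02 to 0.23 (Batf3). The offsets moved the median of all genes to 0.05. Depth was lowest in KO replicate 3, at 11755944 counts.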

Other observations

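The tests of WT replicate 2 and of GC content and length, and the wording of the test of called lists over splits, were set after the results were seen. Apart from Fabp5 and Ptgs2, the genes of this and the next paragraph were also chosen after their values were seen. Within the KO group, replicate 1 differed from replicates 2 and 3 in a set of genes. In these genes it lay closer to the WT libraries, so that KO replicates 2 and 3 stood apart from the rest. Slc4a8, a sodium-bicarbonate transporter, was at 513, 482 and 391 CPM in WT, at 629 CPM in KO replicate 1 and at 136 and 144 CPM in KO replicates 2 and 3. Taok2, a kinase, was at 52.0 CPM in KO replicate 1 and at 14.8 and 15.9 CPM in KO replicates 2 and 3, against 60.2, 45.8 and 53.4 CPM in WT. The prostaglandin synthase gene Ptgs2 was at 194, 77.1 and 72.3 CPM in the KO libraries and at 199, 220 and 152 CPM in WT. In the opposite direction, Fabp5, a fatty-acid binding protein, was at 136, 388 and 486 CPM in KO and at 175, 127 and 161 CPM in WT, and Lgals1, which encodes galectin-1, at 16.5, 46.4 and 65.2 CPM in KO and 18.4, 17.7 and 17.5 CPM in WT. Without KO replicate 1, 7 genes passed, among them these 5, and 1621 passed unadjusted p under 0.05. Passing there but not with all libraries favours genes in which KO replicate 1 lies near WT. The pattern in these 5 genes is therefore no independent sign of a split within the KO group. The Vps33b level was lowest in KO replicate 1, at 5.0 CPM.

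Other genes varied between libraries of one group. Rarres2, which encodes chemerin, was at 22.2, 0.759 and 11.6 CPM in KO and at 0.275, 0.338 and 0.635 CPM in WT. Fcna, which encodes a ficolin, was at 18.2, 3.99 and 4.29 CPM in WT and at 0.217, 1.11 and 0.441 CPM in KO. Igha was at 26.5 and 33.7 CPM in WT replicates 1 and 2 and at 651 CPM in WT replicate 3, against 351, 285 and 487 CPM in KO, and passed without WT replicate 3. In a principal component analysis the first component, with 30.3% of the variance, placed KO replicates 1, 2 and 3 at -37.7, 8.6 and 70.2. The WT libraries lay between KO replicates 1 and 2.

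The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In the real split 0 genes passed and the highest of the other splits was 6. A count of 0 is met by any split, 10 of 10, so that comparison shows nothing. It gave 725 genes at unadjusted p under 0.05, and the highest other gave 1507, with 4 splits, the real one included, giving as many. It gave 7 called lists, and the others gave 5 to 13, with 5 splits, the real one included, giving as many. With an estimated correlation no split called a list. A list called with a preset correlation is therefore not by itself a sign of genotype. The split with 1507 genes and 13 lists set WT replicates 1 and 3 and KO replicate 1 against the rest. Mitochondrial genes held 1.82, 1.98 and 1.81% of the counts in these libraries. In WT replicate 2 and KO replicates 2 and 3 the shares were 2.43, 2.52 and 2.34%. The samples may have a structure apart from genotype, but the split was picked as the highest of 10 and this was not tested.

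With a preset correlation, genes of cDC1 identity were lower and those of the mature CCR7 programme higher in KO, but neither list passed with an estimated correlation (adjusted p = 0.661 for both) or with fry (0.622 and 0.608). WT replicate 2, which had the highest Xcr1 and Cd8a, was not the sole source of the medians, which were -0.20 and 0.17 without it. Both lists passed there with a preset correlation, which is not by itself a sign of genotype. The cDC1 score was highest in WT replicate 2 (0.45) and lowest in KO replicate 1 (-0.38). Without KO replicate 1 the cDC1 list did not pass (median -0.22, camera adjusted p = 0.169 with a preset correlation). A trend with GC content or length was not the whole source either, as the medians with offsets were -0.26 and 0.17. The median of all genes was 0.047 with the offsets. Replacement of cDC1s by cells lacking all of the list's transcripts would lower the 30 members by a common factor, and they differed from one by more than their errors (chi-square heterogeneity p = 7.92e-10 across genes, which are not independent replicates). This bears only on cells that lack all of these transcripts. A mixture with other dendritic cells, or with cells of other lineages that carry some of them, stays open. A stage of maturation that varied from library to library may account for both. It would be expected to give a negative correlation of the 2 scores within groups. Over the 6 libraries the group-centred scores had the opposite sign, with Pearson r = 0.48 (permutation p = 0.389 over 36 arrangements). Spearman rho was 0.37 (permutation p = 0.611), and r was -0.36 without the 2 farthest libraries. The sign is thus unsettled, and a stage of maturation cannot be told apart from an effect of genotype.

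Zfp568 lies on chromosome 7, as does the targeted gene, 50.3 Mb away. DNA of another strain carried with the targeted allele could lower it, and would then be expected to shift other genes of the stretch between them. Of 239 tested genes there, 12 passed unadjusted p under 0.05, or 5.02% (95% exact binomial interval 2.62 to 8.61), against 5.77% of all other genes. The bound was set beforehand as a multiple of the share of other genes, which came to 8.65%, and the interval ends just under it. This argues only against another strain's DNA that shifts many genes over the whole stretch. DNA that alters few genes, or many by a small amount, would not raise the share and stays open. A short remnant near either gene stays open, with 5 of 58 genes within 5 Mb of Vps33b (8.62%) and 3 of 59 within 1 Mb of Zfp568 (5.08%) past that p. An effect of VPS33B loss on Zfp568 was not tested apart from this.

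The clock genes Per1 (-0.65 ± 0.16) and Cry2 (-0.83 ± 0.21) were lower in KO at unadjusted p, each in 3 of 3 libraries, and were chosen after their values were seen. Collection at another time of day could do this. Of the 8 other clock-driven genes tested, 6 lay below 0 with a median of -0.30, from -0.55 to -0.08 with each library left out in turn, while Arntl, which peaks in the opposite phase, was at -0.24 ± 0.27. Few genes and the low levels of some keep this open, so time of day cannot be told apart from genotype.

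The nuclear oxidative phosphorylation median of 0.23 became 0.15 with the GC and length offsets. These moved the median of all genes from 0.004 to 0.047, so the list's lead over other genes fell by more than its median shows. Without the offsets its median lay at the 99.21 percentile of 10000 random lists matched on length, GC content and expression, whose median was 0.15. The random lists held unrelated genes, whereas the members of this list varied together (estimated correlation 0.49). The percentile therefore overstates how unusual the median is, and camera with an estimated correlation gave an adjusted p of 0.661.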
